A study of Mus musculus with 6 samples.

How the data were processed

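The measurements were RNA sequencing profiles of 6 libraries of C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes when its serum is withdrawn. Per the labels, myotubes at 5 days of differentiation received 100 ng per ml of recombinant mouse RANKL for 72 h (3 libraries) or vehicle (3 libraries). RANKL is the ligand of the receptor RANK, known for its part in osteoclast formation. Per the labels' protocols, RNA was extracted with Trizol and the miRNeasy kit, and libraries were read on an Illumina HiSeq in paired-end reads of 75 bases. The labels state that isolation and sequencing were done together for all of these cells, so no batch of these steps separates the groups, and culture or treatment batches are not stated. Nothing in the labels says that the replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

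FastQC, STAR, edgeR and the build mm10 are named in the submitters' processing notes, without versions or roles. The read counter, the gene annotation and the use of strand in counting are not given in the sources used here. The table of raw counts that the authors deposited holds whole-number counts for 12625 gene symbols, followed by 4708 lines with no gene and no value, which hold no part of any library's total and were left out. In every gene of that table the third-highest library had at least 0.504 counts per 1000000 (CPM), which shows that the authors had removed low genes before deposit, by a rule that is not stated. Genes below that level are not analysed here, and Tnfrsf11a (RANK) and Tnfsf11 (RANKL) are among the genes not analysed here. The other table that the authors deposited holds log2 values. Compared with the raw counts, these values are log2 RPKM (RPKM being CPM per kilobase of gene) with a scaling factor per library. The header names neither unit nor log base, so this reading rests on the values.

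Total counts per library lay between 32732604 and 39677999, and 3 counts, the limit that a count of 0 allows in a library, correspond to 0.0772 to 0.0906 CPM. Such limits and the intervals of count ratios cover counting error only, while the 95% intervals of log2 fold changes rest on edgeR's test and include the spread between samples. Counts of library pairs within a group differed by 3.39 to 9.52 chi-square units per gene over genes with at least 20 counts, well above sampling noise, so all 6 libraries were kept as separate samples.

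Groups were taken from the labels. The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (which removed 0 genes), the quasi-likelihood F test and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Fold changes are RANKL over vehicle, and the standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. CPM values use each library's scaled total. The 22 gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, and each list needed at least 5 measured genes. Lists overlap in part: Saa3, Ccl2 and Cxcl1 each stand in more than one. The design, the lists, the alternatives and the naming rule were fixed before the data were examined.

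The rule named RANKL, its receptor and its decoy receptor whatever their values. It then took the 6 highest and 6 lowest fold changes among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, passing over symbols that only number a gene model. From each list it took up to 2 members past the threshold by smallest p, or the member with the smallest p where none passed. This gave 47 genes, of which 4 are not reported here. A further 78 genes were taken after their values were seen. Some of them are not named in the text, which marks the others as such.

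Gene positions come from GENCODE M21 on the mm10 build, used for 12176 symbols directly and for 378 through an older name, while 71 symbols found no match. Of the 125 genes taken by the rule or afterwards, 7 share exons with another gene on the same strand (Parp14, Tapbp, Egfl7, Gbp7, Ifi47, Igtp and Traf5) and 37 with a gene on the opposite strand. Their counts are uncertain to that extent, since the assignment of shared reads is not stated. Where the counts were too few for a fitted fold, ratios of summed counts are given with exact binomial 95% intervals. The steps were tested on simulated data for 12625 genes in 3 RANKL and 3 vehicle libraries. There, the genes given a change of log2 0.3 or 1 all had a mean of at least 1 CPM, so recovery below that level was not tested. Of these changes, 74% of those of log2 0.3 and 100% of those of log2 1 were recovered. Of the calls 7.76% were unchanged genes, and a shifted list was called while 0 of the 21 other lists were. With an added trend on gene length, spanning log2 0.5 from the shortest to the longest gene, the main test called 4760 unchanged genes, and 10 once the trend was removed. That trend was a smooth function of the same gene length that the removal models, so its removal was bound to work well. It was also stronger than the real trend, with a median log2 fold change of 0.0386 in the shortest of 5 length classes and -0.0281 in the longest. These simulated genes varied independently, which real genes do not.

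Alternatives were DESeq2 size factors in edgeR, scaling to total counts, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma with a trend on the authors' log2 values, the replicate number as a block, and each library left out. For lists, camera with an estimated correlation and fry were added. Removing a smooth trend on gene length or on GC content from each library was chosen after seeing the data.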

Results

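Gene counts were compared between C2C12 myotubes given RANKL for 72 h and myotubes given vehicle, with 3 libraries in each group. The vehicle libraries held 39677999, 33566746 and 37017967 counts and the RANKL libraries 37445933, 33580991 and 32732604. The first principal component of log2 CPM held 60.2% of the variance and separated the groups. The second, with 14.4%, set RANKL replicate 1 apart from RANKL replicate 3. The precursor of ribosomal RNA, Rn45s, took 0.558% to 0.898% of counts, with both groups spanning most of that range. The question the design addresses is what RANKL does to cultured C2C12 myotubes. No other ligand and no inactivated protein stands among the samples analysed here, so the comparison is between this RANKL preparation and its vehicle.

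RNA of several chemokines, of the complement component C3 and of the acute phase protein Saa3 rose under RANKL. Cxcl1, a neutrophil chemokine, rose 149-fold, from 0.219 ± 0.0466 to 33.4 ± 4.50 CPM (mean ± SD, n = 3 in each group). Ccl2, the main monocyte chemokine, rose 25.0-fold, from 3.75 ± 1.04 to 94.4 ± 3.94 CPM. C3, central to the complement cascade, rose 99.1-fold to 10.4 ± 0.992 CPM. Saa3 had 3 counts in all vehicle libraries together and 826 in the RANKL libraries, a ratio of 286 (95% interval 97.7 to 1390).

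Among genes with a mean of at least 1 CPM, the 6 that the rule ranked highest by fold change were Saa3, Cxcl1, C3, Cxcl5, Ccl2 and Cxcl16. Their log2 fold changes were 7.22 ± 0.17 (SE) for Cxcl1, 6.63 ± 0.22 for C3, 4.87 ± 0.19 for Cxcl5, 4.64 ± 0.09 for Ccl2 and 3.28 ± 0.21 for Cxcl16. Adjusted p by edgeR's quasi-likelihood test ranged from 3.03e-13 for Ccl2 to 1.81e-07 for Cxcl16, and for each gene all 3 RANKL libraries lay above all 3 vehicle libraries. On mm10, Cxcl1 lies on chromosome 5 from 90891241 to 90893115 and Cxcl5 on the same chromosome from 90759360 to 90761624. Ccl2 lies on chromosome 11 from 82035571 to 82037453, beside Ccl7 from 82045712 to 82047525. C3 lies on chromosome 17 from 57203970 to 57228136, Saa3 on chromosome 7 from 46711998 to 46715700 and Cxcl16 on chromosome 11 from 70453983 to 70459984. All are protein-coding. The exons of Cxcl16 overlap those of Zmynd15 on the opposite strand, and reads of the pair cannot be told apart because the use of strand is not stated. Saa3 belongs to a family of similar genes, which makes its counts less certain.

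**Figure D1:**
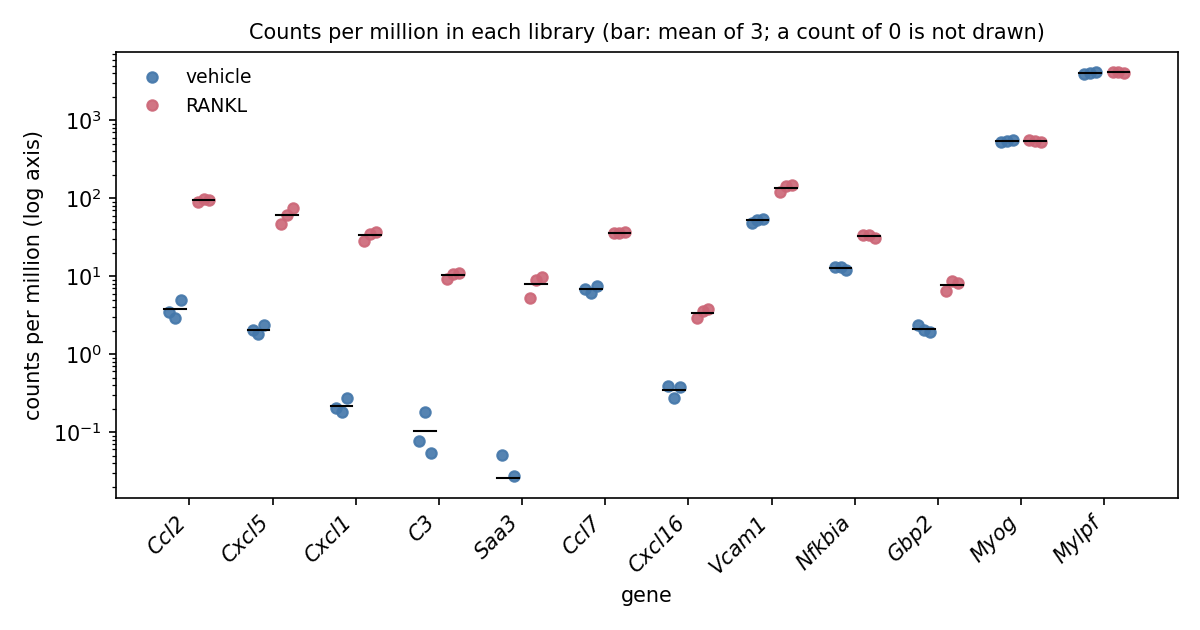
CPM in each library (points, log axis) and the mean of 3 libraries (bars) for 12 genes under vehicle (blue) and RANKL (red). A count of 0, that of Saa3 in vehicle replicate 2, is not drawn. Ccl7, Vcam1, Nfkbia, Myog and Mylpf were chosen after their values were seen. Each of the first 10 genes, from Ccl2 to Gbp2, has all 3 RANKL libraries above all 3 vehicle libraries, while Myog (adjusted p = 0.922) and Mylpf (adjusted p = 0.693) did not pass the test.

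The genes that fell did so by less. Among the lowest by the rule were Fbln7 (an extracellular matrix fibulin), Adra1d (an alpha-adrenergic receptor), Mn1, Lgr5 (a receptor that enhances Wnt signalling) and Ndst4 (a heparan sulphate enzyme). Fbln7 went from 10.4 ± 0.722 to 5.41 ± 0.326 CPM, a log2 fold change of -0.94 ± 0.09 (adjusted p = 8.96e-06). The other 4 lay between -0.91 ± 0.18 for Adra1d and -0.74 ± 0.12 for Ndst4, and each kept its call in every alternative that tested it.

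In all, edgeR called 676 genes higher and 947 lower of 12625 tested, 12.9% of them. Of these calls 41.7% were higher, whereas scaling to total counts gave 1070 higher and 626 lower genes, 63.1% higher, so the balance between the directions rests on the scaling. Most changes were small: 86.2% of called genes had an absolute log2 fold change under 0.5, with a median of 0.28 among higher and -0.19 among lower genes. Above a log2 fold change of 1 stood 58 called genes. Below -1 stood 5, Synpr, Ccin, Cpm, Gpr141 and Adam22 (chosen after their values were seen), each near 1 CPM under vehicle, and each lost its call without at least 1 of the 6 libraries. Adam22 went from a log2 fold change of -1.01 to -0.60 without vehicle replicate 1. The groups did not overlap in 3976 genes (31.5%, against 10% by chance). Without vehicle replicate 1 there were 426 higher and 561 lower genes, without vehicle replicate 2 there were 373 and 537, and without RANKL replicate 2 there were 596 lower genes.

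RANKL's decoy receptor, Tnfrsf11b (osteoprotegerin), had 1.40 ± 0.0271 CPM under vehicle and 1.62 ± 0.231 under RANKL, a log2 fold change of 0.22 ± 0.17 that did not pass the test (adjusted p = 0.447). Of 26 measured RANK signalling components, 6 rose, also 6 adjusted over the list alone, where 1 was lower. Relb and Nfkb2, the NF-kB subunits of the non-canonical branch, rose by log2 0.60 ± 0.05 and 0.34 ± 0.03. The other 4 were Ikbkg, Traf2, Nfkb1 and Traf5, with log2 fold changes of 0.16 to 0.40. Of these, Ikbkg was not called without vehicle replicate 2, nor Traf5 without vehicle replicate 2 or RANKL replicate 2. Relb, Nfkb2 and Nfkb1 also stand in the list of NF-kB response genes, so the rise here is not separate from the rise of that list. Camera called the RANK signalling list higher (adjusted p = 0.00323), but not with an estimated correlation (adjusted p = 0.285). Apart from Relb and Nfkb2, the members that rose were chosen after their values were seen.

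NF-kB response genes rose as a group: 21 of 29 measured members passed the test, 23 adjusted over the list alone. Besides Cxcl1, Ccl2, Cxcl5 and Saa3, these included the feedback inhibitors Nfkbia and Nfkbie, which rose 2.56-fold and 2.38-fold, and the adhesion molecule Vcam1, which rose from 52.0 ± 2.94 to 136 ± 14.2 CPM. Nos2, the inducible nitric oxide synthase, had 2 counts in the vehicle libraries together and 95 in the RANKL libraries, a ratio of 49.4 (95% interval 13.3 to 414). Nfkbia, Nfkbie, Vcam1 and Nos2 were chosen after their values were seen. The list's median log2 fold change was 0.49, with an adjusted p of 1.83e-118 by camera and 0.00129 with an estimated correlation.

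Among chemokines and cytokines 12 of 28 measured members rose and 2 fell, 14 and 3 adjusted over the list alone. Ccl7, the neighbour of Ccl2, rose 5.21-fold to 36.0 ± 0.636 CPM, and Cxcl10, a T-cell chemokine, rose 12.2-fold from 0.0895 ± 0.0539 CPM. Ccl5 went from 3 counts over the vehicle libraries to 69 under RANKL, a ratio of 23.9 (95% interval 7.85 to 119). The 2 that fell were Cxcl14 (log2 fold change -0.44 ± 0.11) and Tnfsf9 (-0.34 ± 0.10). Neither fall was called without vehicle replicate 3 or RANKL replicate 3, nor Cxcl14 without vehicle replicate 1 or RANKL replicate 2, nor Tnfsf9 without vehicle replicate 2 or RANKL replicate 1 or with total count scaling. The adjusted p lay between 0.00083 and 0.0721 for Cxcl14 and between 0.0155 and 0.133 for Tnfsf9 over 16 alternatives. Camera gave an adjusted p of 8.08e-65, and 0.00278 with an estimated correlation. These 5 genes were chosen after their values were seen.

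The STAT3 and acute phase list had 15 of 23 measured members higher, 16 adjusted over the list alone, led by Saa3 and C3. Its adjusted p was 1.39e-25 by camera and 0.0224 with an estimated correlation, and 9 members rose without vehicle replicate 3 and without RANKL replicate 2. Of 25 interferon-stimulated genes 9 rose, 12 adjusted over the list alone. Gbp2, an interferon-inducible GTPase, rose from 2.12 ± 0.244 to 7.77 ± 1.11 CPM, and Parp14 rose 2.17-fold. Isg15 and Ifit3, common markers of a type I interferon response, had log2 fold changes of -0.07 ± 0.24 and -0.01 ± 0.21 and did not pass the test (chosen after their values were seen). The list's adjusted p was 5.75e-10, and 0.0257 with an estimated correlation. MHC class I antigen presentation genes had 10 of 16 members higher, also 10 adjusted over the list alone, and 6 without vehicle replicate 1, vehicle replicate 2 or RANKL replicate 2. Tapbp, which loads peptide onto class I molecules, rose 1.24-fold and H2-Q4 1.58-fold, and the adjusted p was 8.14e-09, or 0.0391 with an estimated correlation. The Gbp and H2 genes have close paralogs, and how reads shared among them were counted is not given in the sources used here.

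Markers of immune cells did not pass the test beside these rises. Of 22 macrophage and osteoclast markers only 5 were measured, with a median log2 fold change of 0.29 and a range from -0.46 to 0.64. So few genes cannot exclude a rise. Among these 5 edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma-trend also called 0. That 1 was Cd14, at 3.62 ± 0.290 CPM under vehicle and 4.44 ± 0.242 under RANKL (log2 fold change 0.29 ± 0.11, adjusted p = 0.105). Among 5 endothelial markers edgeR called 0 and none had an unadjusted p under 0.05, and the other 3 tools called 0; Egfl7 had the smallest p (log2 fold change 0.11 ± 0.22, adjusted p = 0.792). Among 6 adipocyte markers edgeR called 0, with 2 at an unadjusted p under 0.05 and 0 by the other 3 tools, and Plin4 stood at -0.38 ± 0.14 (adjusted p = 0.0824, and 0.0443 without RANKL replicate 1). Of 10 osteoblast markers 1 fell, also 1 adjusted over the list alone, and 0 were called without vehicle replicate 1 or 2, RANKL replicate 1 or 2, or with total count scaling, while 2 had an unadjusted p under 0.05 in the main test. For that list limma-voom called 1, and DESeq2 and limma-trend called 0. Adjusted over the list alone, no adipocyte, macrophage and osteoclast or endothelial marker was called. Camera's adjusted p was 0.489 for the macrophage and osteoclast list, 0.508 for the osteoblast list and for the adipocyte list, and 0.885 for the endothelial list.

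**Figure D2:**
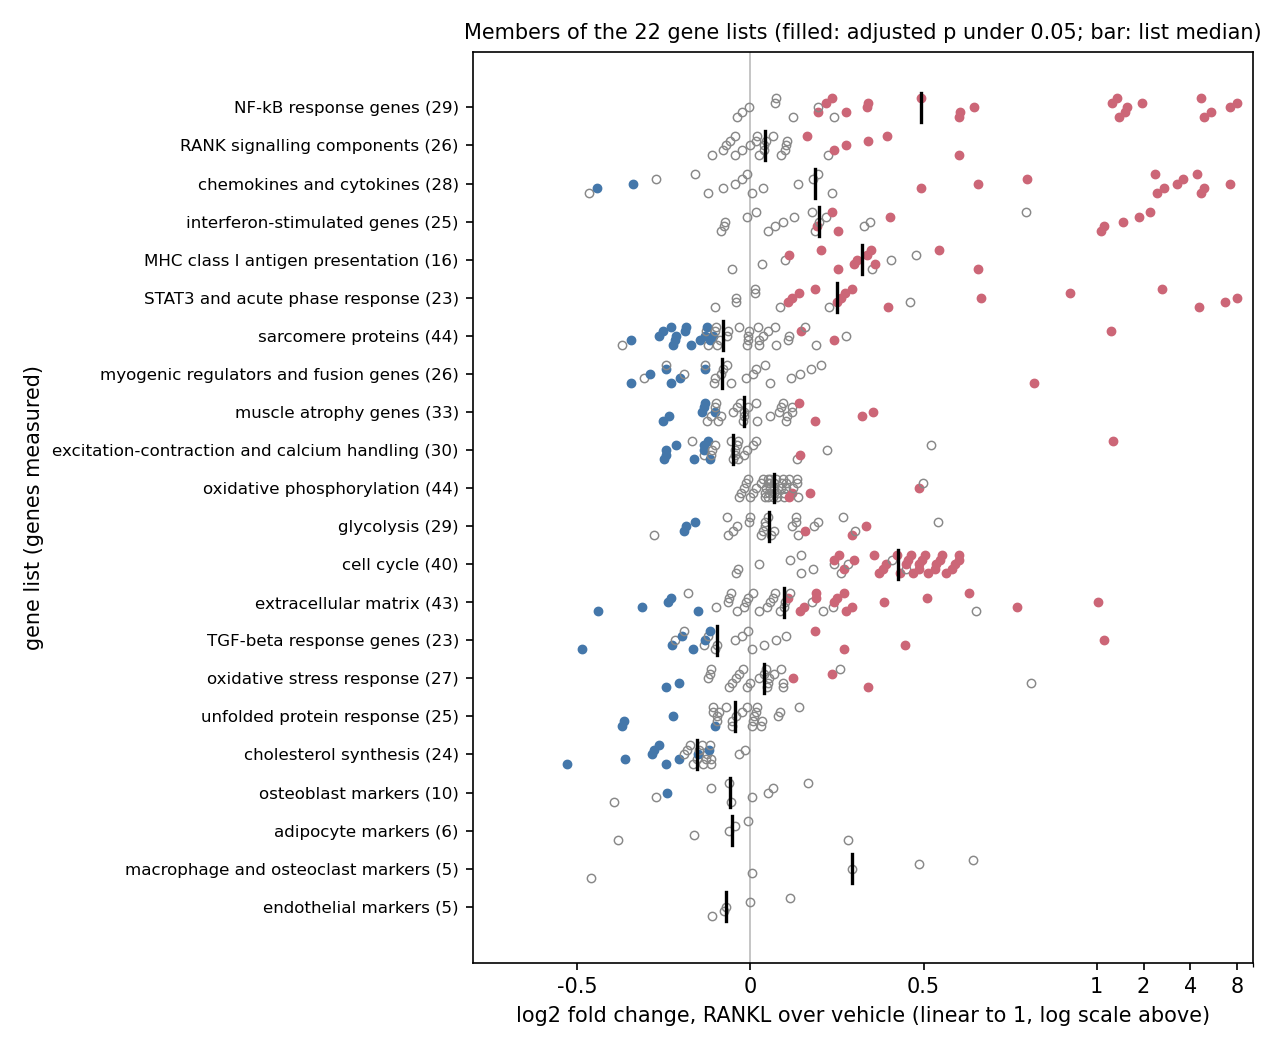
Log2 fold change of each measured member of the 22 gene lists, RANKL over vehicle, on an axis that is linear to 1 and logarithmic above. Filled points passed the test (red higher, blue lower), open points did not, and black bars are list medians, from 0.49 for NF-kB response genes to -0.15 for cholesterol synthesis.

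Part of the contractile apparatus fell slightly. Of 44 sarcomere genes 15 fell and 3 rose, 18 and 5 adjusted over the list alone. Myh8, a perinatal myosin heavy chain, fell from 280 ± 18.6 to 220 ± 14.1 CPM (log2 fold change -0.35 ± 0.05, adjusted p = 0.000439), and Ldb3, a Z-disc protein, from 337 ± 1.31 to 288 ± 1.85 CPM. Skeletal actin, Acta1, fell from 6072 ± 57.0 to 5325 ± 128 CPM, while Mylpf and Tnnt3, a myosin light chain and a troponin T of fast fibres, had log2 fold changes of 0.03 ± 0.04 and 0.05 ± 0.04 and did not pass. The 3 that rose were Cmya5 (1.23 ± 0.36), Xirp2 (0.24 ± 0.05) and Tpm3 (0.15 ± 0.04). Without RANKL replicate 1, Cmya5 stood at 0.54 (adjusted p = 0.144) and Tpm3 at 0.09 (adjusted p = 0.0736), and neither was called without any one vehicle replicate. Fewer sarcomere genes fell without vehicle replicate 2 (8) and without RANKL replicate 2 (9), while 6 rose without RANKL replicate 3. Acta1, Mylpf, Tnnt3 and these 3 were chosen after their values were seen.

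Excitation-contraction and calcium handling genes had 9 of 30 members lower and 2 higher, 12 and 4 adjusted over the list alone. Srl (sarcalumenin) fell from 981 ± 17.8 to 825 ± 44.7 CPM, Cacna1s, the voltage sensor of the muscle calcium channel, from 587 ± 19.1 to 505 ± 5.29 CPM, and Ryr1, the calcium release channel, by 0.25 ± 0.05 on the log2 scale. Pvalb, a calcium buffer of fast fibres, rose 2.41-fold, from 2.04 ± 0.248 to 4.88 ± 1.99 CPM. Its counts in RANKL replicates 1, 2 and 3 were 262, 160 and 99. Trdn rose 1.10-fold, though its call ended without any one vehicle replicate, without RANKL replicate 1 and with the trend on GC content removed. The log2 fold change of Trdn went from 0.14 to 0.09 without RANKL replicate 1 and to 0.08 with that trend removed. Of 26 myogenic regulators and fusion genes 6 fell and 1 rose, also 6 and 1 adjusted over the list alone. Cdh15, the M-cadherin of myoblast adhesion, fell by 0.29 ± 0.03 and Mef2d by 0.24 ± 0.04 on the log2 scale. Myf6 rose 1.76-fold, from 4.50 ± 0.421 to 7.87 ± 2.27 CPM, and Myog had a log2 fold change of 0.01 ± 0.03. Ryr1, Pvalb, Trdn, Myf6 and Myog were chosen after their values were seen. Leaving out vehicle replicate 2 or RANKL replicate 2 left 4 calcium handling genes lower.

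Camera called these 3 muscle lists lower, with an adjusted p of 0.00333 for sarcomere, 0.00432 for calcium handling and 0.0103 for myogenic genes. With an estimated correlation the adjusted p was 0.387, 0.415 and 0.285, and without RANKL replicate 3 it was 0.106, 0.0839 and 0.0621, so none of the 3 list calls held. Splits of the 6 libraries that mix the groups gave each list an adjusted p as low or lower in 2, 3 and 3 of 9 cases.

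Atrophy genes moved in both directions: of 33 measured, 4 rose and 6 fell, 9 and 11 adjusted over the list alone. Fbxo32, the ubiquitin ligase atrogin-1, rose from 142 ± 2.73 to 177 ± 8.70 CPM (log2 fold change 0.32 ± 0.04, adjusted p = 7.22e-05). Trim63, the ligase MuRF1, had a log2 fold change of 0.12 ± 0.04 with an adjusted p of 0.0599. It passed with total count scaling (0.0229), without RANKL replicate 3 (0.00936) and with the trend on GC content removed (0.0224). The other 3 that rose were Fbxo30, Bnip3 and Bnip3l, of which Bnip3 and Bnip3l were not called without vehicle replicate 2, nor Bnip3 without vehicle replicate 1. Without RANKL replicate 1, Bnip3 went from a log2 fold change of 0.35 to 0.21. Asns, which makes asparagine, fell by 0.25 ± 0.04 on the log2 scale. The list as a whole was not called (adjusted p = 0.778), its median (-0.02) and its mean (0.0003) differ in sign, and with total count scaling 8 members rose and 3 fell. Leaving out vehicle replicate 2 gave 2 higher and 2 lower, and 3 fell without vehicle replicate 1 or RANKL replicate 1. Trim63, Fbxo30, Bnip3 and Bnip3l were chosen after their values were seen.

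Cell cycle genes rose: 28 of 40 measured members passed the test, 34 adjusted over the list alone, with a median log2 fold change of 0.43. Mki67, a marker of cycling cells, rose from 35.5 ± 2.09 to 52.1 ± 3.83 CPM, and Cdk1, the mitotic kinase, from 9.62 ± 0.587 to 13.7 ± 0.220 CPM. Their log2 fold changes were 0.55 ± 0.06 (adjusted p = 1.9e-05) and 0.50 ± 0.07 (adjusted p = 0.000361). Camera's adjusted p was 1.07e-17, but 0.153 with an estimated correlation. Leaving out vehicle replicate 2 gave 14 higher members, and leaving out another library 19 to 28.

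Extracellular matrix genes split, with 15 of 43 higher and 5 lower, 19 and 7 adjusted over the list alone. Tnc (tenascin C) rose from 176 ± 17.5 to 272 ± 25.1 CPM and Postn (periostin) from 386 ± 18.2 to 657 ± 114 CPM. Thbs1 (thrombospondin 1), an abundant transcript, fell from 2397 ± 52.4 to 1769 ± 113 CPM, and the other 4 that fell were Timp3, Adamts5, Mmp2 and Col12a1. Of these, Mmp2 was not called without vehicle replicate 2 or 3, nor Col12a1 without RANKL replicate 2. Mmp2 went from a log2 fold change of -0.23 to -0.14 without RANKL replicate 1, and Col12a1 from -0.15 to -0.09 with the trend on gene length removed. Camera called the list higher (adjusted p = 0.00257), with 0.283 for the estimated correlation, and 1 of 9 mixed splits gave an adjusted p as low. TGF-beta response genes had 4 of 23 higher and 6 lower, 4 and 7 adjusted over the list alone, with no list call (adjusted p = 0.508) and 4 higher and 3 lower with total count scaling. Without vehicle replicate 1, vehicle replicate 2 or RANKL replicate 2, 3 fell, and without vehicle replicate 3 or RANKL replicate 2, 2 rose. Tagln, an actin-binding protein of smooth muscle, rose 1.36-fold. Junb and Ltbp2 also rose, neither called without vehicle replicate 3 or RANKL replicate 2, nor Junb without vehicle replicate 2, nor Ltbp2 without vehicle replicate 1. Apart from Tnc, Thbs1 and Tagln, the genes named here were chosen after their values were seen.

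Of 24 cholesterol synthesis genes 9 fell slightly, 15 adjusted over the list alone, with a list median log2 fold change of -0.15 (-0.07 without RANKL replicate 1). Ebp, an enzyme of a late step, fell by 0.21 ± 0.04 on the log2 scale. Camera's adjusted p was 1.08e-07, but 0.387 with an estimated correlation, and 4 of 9 mixed splits gave an adjusted p as low. Members lower numbered 5 without vehicle replicate 1, 4 without vehicle replicate 2 and 16 without RANKL replicate 3. Oxidative phosphorylation genes had 4 of 44 members higher, 3 adjusted over the list alone: Cox6c (0.17 ± 0.03), Ndufs1 (0.12 ± 0.03), Uqcrfs1 (0.11 ± 0.03) and Cox8b (0.49 ± 0.12). The list was called higher (adjusted p = 0.000668), but not with an estimated correlation (adjusted p = 0.603) or once a trend on gene length was removed (adjusted p = 0.157), and 3 of 9 mixed splits gave an adjusted p as low. Members higher numbered 1 without vehicle replicate 2, 2 without vehicle replicate 1 or RANKL replicate 2, and 9 without RANKL replicate 3 or with total count scaling. Among these 4, Ndufs1 was not called without vehicle replicate 2 or 3, Uqcrfs1 without any one library, and Cox8b without any one vehicle replicate or RANKL replicate 2. Cox8b stood at 0.31 without RANKL replicate 1, and Cox6c at 0.10 with the trend on gene length removed, both still called. Uqcrfs1 and Cox8b were chosen after their values were seen.

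The remaining 3 lists were not called by the main camera test. Of 29 glycolysis genes 3 rose and 3 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.379, and 0.0223 with 8 higher members without RANKL replicate 3), and 7 rose with total count scaling. Pgk1 rose 1.26-fold and Hk2, the hexokinase of muscle, fell by 0.18 ± 0.03 on the log2 scale, and the other 4 were Ldha and Pfkfb3, higher, and Pygm and Hk1, lower. Of 27 oxidative stress genes 3 rose and 2 fell, 4 and 3 adjusted over the list alone (adjusted p = 0.497), while 1 rose without vehicle replicate 2, 5 rose with total count scaling and 1 fell without RANKL replicate 2. Sod2, the mitochondrial superoxide dismutase, rose 1.18-fold, Ucp2 fell by 0.21 ± 0.04 on the log2 scale, and the other 3 were Gpx3 and Prdx6, higher, and Osgin1, lower. Of 25 unfolded protein response genes 4 fell, 6 adjusted over the list alone (adjusted p = 0.0534), and 2 fell without vehicle replicate 1 or 2 or RANKL replicate 2 or 3, or with total count scaling. The list was called lower without vehicle replicate 1 (adjusted p = 0.0367), by fry (0.00695), and with the trend on gene length (0.0371) or GC content (0.0337) removed. Herpud1 fell by 0.22 ± 0.03 and Chac1 by 0.37 ± 0.08 on the log2 scale, and the other 2, Trib3 and Atf4, were not called without any one vehicle replicate, without RANKL replicate 2 or 3 or with total count scaling, nor Atf4 without RANKL replicate 1. Ldha, Gpx3 and Prdx6 were not called without vehicle replicate 2 or 3, Ldha and Prdx6 also not without vehicle replicate 1 or RANKL replicate 2, nor Osgin1 without RANKL replicate 2. Without RANKL replicate 1, Ldha went from a log2 fold change of 0.16 to 0.09 and was not called, and Gpx3 from 0.34 to 0.19. Apart from the first pair given for each list, these genes were chosen after their values were seen.

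Across the 22 lists camera called 9 higher and 4 lower. With an estimated correlation 5 stayed higher, those of NF-kB response genes, chemokines and cytokines, STAT3 and acute phase response, interferon-stimulated genes and MHC class I genes, and 0 were lower by that test, also at an unadjusted p under 0.05, while fry called 2 lower, the myogenic and the unfolded protein response lists (adjusted p = 0.0451 and 0.00695). Among the 9 splits that mix the groups, camera at the preset correlation called up to 10 lists in one direction, more than in the real split. No mixed split gave an adjusted p as low as the real one for these 5 lists, for cell cycle or for RANK signalling. Each mixed split still holds part of the RANKL difference, and the rest adds to the spread within its groups. The mixed splits are therefore no fair chance level, and this comparison cannot decide whether a list call is due to chance. The margins differed: for RANK signalling camera's adjusted p was 0.00323, against 0.00353 in the nearest mixed split. Cell cycle was called in 6 of the 9 mixed splits, with a lowest adjusted p of 1.89e-10 against 1.07e-17. For NF-kB response genes the lowest was 9.75e-08 against 1.83e-118.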

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

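The alternatives that remove a trend on gene length or GC content were chosen after seeing the data, and the others were fixed before the data were examined. No call of a gene by the main test changed sign under any of the 16 alternatives computed for genes. The genes higher and lower, 676 and 947, stayed within 1.5 times of those counts with DESeq2 size factors (676 and 945), a filter of 1 CPM (677 and 925), DESeq2 (535 and 809), limma-voom (656 and 954), limma-trend on the authors' log2 values (528 and 678), the length trend removed (840 and 894) and the GC trend removed (680 and 758). Of the 1623 calls, limma-voom kept 1586, the length trend removed 1447, DESeq2 1319, the GC trend removed 1199 and limma-trend 1157, so similar totals hide changed membership. The comparison with no filter says nothing, since the main filter removed 0 genes. Scaling to total counts gave 1070 higher and 626 lower, with 1302 of the 1623 calls kept. It moved the median log2 fold change of all genes from 0.0047 to 0.0354, and by construction it differs only in one factor per library. Leaving out 1 library gave 373 to 746 higher and 537 to 880 lower genes, with 893 to 1338 of the 1623 calls kept, and the cause was not tested.

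The lists called higher and lower, 9 and 4, became 5 and 0 with an estimated correlation, with 0 lower also at an unadjusted p under 0.05, and 8 and 2 by fry. Of those 2, the myogenic list is among the 4, and the unfolded protein response list is not. Leaving out 1 library gave 9 to 10 higher and 1 to 5 lower lists, the lowest without RANKL replicate 3, and the cause was not tested. Of 106 called genes taken by the rule or afterwards, 76 kept their call in all alternatives that tested them. The 30 others lost it in 1 to 10 alternatives, without a change of sign. Among uncalled values, 13 for 6 named genes and 4 for 3 lists changed sign, near 0.

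With the number as a replicate block, 730 genes were higher and 1008 lower, and 1564 of the 1623 calls were kept. The correlation of deviations between samples that share a number was 0.118, 0.053 and 0.018, which does not show pairing, although 4 of 6 samples correlated best with their own number. The labels do not say what the numbers mark, so whether they pair the samples stays open. The block ended no list call. Genes with few counts had a larger SE: near 1 CPM, Isg15, Mx2 and Egfl7 had 0.24, 0.325 and 0.219 on the log2 scale. Gbp5, with 0 counts under vehicle, had 0.722, against 0.0287 for Ldb3 at 288 CPM under RANKL. The SE also includes the spread between samples, so the part due to depth was not tested.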

Other observations

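Genes outside the fixed lists also changed, and those named here were chosen after their values were seen. Zc3h12a, whose product Regnase-1 degrades mRNAs of inflammatory genes, rose 2.94-fold from 9.45 ± 0.563 to 27.8 ± 1.61 CPM (n = 3 in each group, edgeR adjusted p = 1.67e-09). Ptx3, a soluble pattern recognition protein, rose 6.37-fold, the lymphangiogenic factor Vegfc 2.85-fold, and Enpp2, the enzyme autotaxin that makes lysophosphatidic acid, 2.81-fold. The receptors Tlr2 and Tnfrsf1b, the latter a receptor of TNF, rose 1.54-fold and 1.61-fold. Gbp5 had 0 counts in the vehicle libraries and 104 in the RANKL libraries, at least 36.1-fold higher against a floor of 3 counts over the group. Among genes that fell, Egr3, a transcription factor of muscle spindle development, went from 92.2 ± 4.67 to 60.6 ± 2.64 CPM, Hopx from 11.2 ± 0.823 to 7.05 ± 0.691 CPM, and the hormone Fgf21 from 12.5 ± 1.03 to 8.20 ± 1.25 CPM. All of these calls were kept in each alternative that tested the gene.

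A screen of 197 gene families that share a symbol stem and have at least 8 measured members, also chosen after seeing the data, called 4 families higher and 2 lower by camera at the preset correlation. The Cxcl chemokines (8 measured, 5 higher, 1 lower) had an adjusted p of 9.95e-41, and 0.0583 with an estimated correlation. The Ifi genes (8 measured, 5 higher) had one of 0.000294, and 0.971 with an estimated correlation. Ribosomal protein genes were called higher, with 6 of 47 Rpl and 7 of 43 Rps genes passing, and lost the call once the trend on gene length was removed (adjusted p = 0.639 and 0.959) and with an estimated correlation (adjusted p = 0.971 for both). Myosin heavy chains of the Myh stem (8 of 11 lower, adjusted p = 5.29e-05) and genes of the Myo stem (6 of 16 lower, adjusted p = 0.00411) kept it with that trend removed (adjusted p = 0.000979 and 0.0354), but not with an estimated correlation (adjusted p = 0.971 for both). Across genes, log2 fold change fell with gene length (Spearman's rho = -0.2, genes not being independent replicates), from a median of 0.0386 in the shortest of 5 length classes to -0.0281 in the longest.

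The tests on myotube share, myoblasts and interferon families, and the counts of genes in other splits, were chosen only after the results were seen. The first pattern is the fall of contractile and calcium handling genes, 24 of which were called lower. A trend of fold change with gene length could give such a fall, but 22 of the 24 were still called lower with the trend removed, which argues against it as the whole cause. The sarcomere genes had a median length of 3.34 kb. The length classes at 2.99 and 4.16 kb had median log2 fold changes of 0.00217 and -0.00996. Removing the trend was therefore bound to change a gene of that length little. A smaller share of myotube RNA would lower sarcomere genes by a common amount if myotubes alone expressed them all. That condition was not tested. The 95% intervals of 25 of 44 sarcomere genes left out the list median of -0.0793, against at most 5 by chance if genes were independent. With 1 library left out or total count scaling, 19 to 27 left out each fit's own median (as small as -0.0389, without RANKL replicate 3). Real genes do not vary independently, so the bound of 5 is only approximate. The values speak against a common fall of all 44, but not against a smaller share that moves members unequally. That myosin and calcium channel genes respond selectively to RANKL stays an open hypothesis. A smaller share of myotube RNA and culture variation also stay open, the latter since the labels name no separate cultures.

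The second pattern is the rise of cell cycle genes. Of the 28 members called higher, 28 were still called with the length trend removed and 27 with the GC trend removed, so neither trend is a likely whole cause. The cell cycle genes had a median length of 3.06 kb, and the length class at 2.99 kb had a median log2 fold change of 0.00217. Removing the length trend was therefore bound to change a gene of that length little. A larger share of undifferentiated myoblasts would raise their regulators: Pax7 had a log2 fold change of -0.31 (95% interval -0.815 to 0.201), Myf5 one of 0.14 (-0.014 to 0.297) and both a median of -0.083. Neither interval lies above 0, yet that of Myf5 reaches past 0.214, the bound below which both had to end, so more proliferating myoblasts and more cycling per cell cannot be told apart from these 2 genes. Mki67, at 52.1 CPM under RANKL beside 35.5 under vehicle, shows that RNA of this marker was present in both groups, while cycling itself was not measured.

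The third pattern is that guanylate-binding and IRG GTPase genes were higher while Ifit, Isg, Mx and Oas genes were not called. Of 6 GTPase genes 5 were called higher (Gbp2, Gbp3, Gbp7, Ifi47 and Irgm1, but not Igtp at 0.18 ± 0.15), and of 7 genes of the other families edgeR, DESeq2, limma-voom and limma-trend each called 0, with 1 at an unadjusted p under 0.05 by edgeR, Ifit1 at 0.80 ± 0.27 (adjusted p = 0.0646). The means of 1.17 and 0.133 gave p = 0.0111 in a two-sided exact permutation test over 1716 assignments of genes, but the families were picked after their values were seen, so this does not decide whether 2 branches of interferon-stimulated genes respond differently. The upper 95% bound of 6 of the 7 lay below 1.27, the median of the GTPase genes, yet so did those of Irgm1 (0.355) and Igtp, and 5 of the 7 allow a rise as large as the 0.25 of Irgm1. Counts too low to show a small rise and a real difference between the families therefore cannot be told apart, and reads shared among Gbp paralogs were not tested.

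The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, gave counts as large: 676 higher and 947 lower, against 0 in either direction in the other 9. These 9 held 166 to 572 genes at an unadjusted p under 0.05, where 631 would be expected by chance. Each group in them holds both treatments, so the RANKL difference adds to the spread within groups and holds back calls. Their 0 is therefore no fair chance level for 676 and 947. For lists, a split and its mirror count as one, so the larger of both directions was taken in each other split. Counted so, 2 of the 10 splits gave as many as the 9 higher and 9 gave as many as the 4 lower, with 10 the highest of the others in each case. The split with 10 set vehicle 1, RANKL 1 and RANKL 2 against the rest. These other splits still hold part of the RANKL difference, since each puts 2 libraries of one group against 1: NF-kB response genes were called in all 9.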
